A study of Mus musculus with 24 samples.

How the data were processed

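Total RNA was sequenced in 24 mouse libraries. Per the labels, RNA was extracted with Trizol, ribosomal RNA was removed with RiboMinus, and the libraries were strand-specific. The submitters' processing notes name TopHat2 2.0.10, HOMER 4.8 and the mm9 genome build, with no settings for counting. The deposited tables hold raw read counts per RefSeq gene for 24421 genes, with no normalization, as the file names state and as the values, whole numbers throughout, show. One table covers the 21 tissue libraries. The other covers the 3 fibroblast libraries, each with a column for all reads and a column for the reads of each parental allele. The allele columns were read as CAST/EiJ (cas) and 129S1/SvImJ (mus) from the column names and the strain label. How reads were assigned to alleles is not stated in the sources used. Of each fibroblast library's reads, 29.1% to 29.5% carried an allele.

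A spreadsheet had turned 27 symbols into dates, of which 26 were repaired through their RefSeq accession and 1 had no match. No symbol occurred more than once. Every column of both tables was matched to a sample.

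In units of 1e+06 counts, the tissue libraries held 3.74 to 15.9 (median 10.9), with medians of 11 in 7-week brains, 6.15 in livers and 15 in aged brains. The labels do not say that replicates are separate animals, so p-values measure only the spread between samples.

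Replicated groups were compared with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test on raw counts, TMM scaling, filterByExpr on the group, prior count 3). The 11 brain libraries of 7-week mice were fitted together, with 15284 genes kept, and the 6 livers separately, with 11817 genes kept. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Brain contrasts were the Aza effect in each Xist genotype, the deletion effect under each treatment, deletion plus Aza against neither, the interaction, and the average of each effect. Levels are given as TMM-scaled counts-per-million (CPM), as mean ± SD over libraries.

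Replicate numbers were checked for pairing. After removal of group means, libraries with the same number correlated above 0.1 in 15 of 15 brain pairs (median 0.408) and in 3 of 3 liver pairs. Pairs with different numbers reached at most 0.113 in brain and 0.047 in liver. The numbers thus pair the samples, and every comparison was also fitted with replicate number as a block. The 2lox/2lox saline group has no replicate 1.

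X-linked genes without the listed escapees, Xist and Tsix (517 in brain, 318 in liver) were compared with autosomal genes by limma 3.58.1 camera with a preset correlation of 0.01, and again with the correlation estimated. A per-library index, the mean log2 CPM of X-linked genes minus that of autosomal genes, was compared by exact 2-sided permutation. With 3 libraries against 3 the smallest p is 0.1. The same index was taken for listed escapees. A fixed set of 52 gene lists for X-linked classes, cell types, tissue functions and stress responses was tested by camera in the same way, adjusted over the lists of a tissue. Of their 948 distinct genes, 932 were found in the tables.

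Lists, comparisons, tests and the rule for named genes were chosen before the data were examined. The rule names up to 10 called genes per direction by size of change, with a mean of at least 1 CPM and no overlap between groups (dropped for averages). Where fewer than 10 genes were called, it adds the 5 genes with the smallest unadjusted p. Xist, Tsix, Jpx, Ftx, Mecp2, Cdkl5, Fmr1 and Dnmt1 are always included, with called X-linked genes. Up to 4 members of each list described are taken by p.

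Single libraries (aged brains and fibroblasts) were compared as ratios of CPM with exact conditional binomial 95% intervals, for genes with at least 50 counts over the pair and 5 CPM. For these, the rule names the 10 largest changes per direction. A list's median log2 ratio was placed among 10000 random lists matched on expression. Allele shares have exact (Clopper-Pearson) 95% intervals and use genes with at least 20 allelic reads in each library. A count of 0 is bounded by 3 counts per library. Intervals and bounds cover counting error only.

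Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, the replicate block, autosomal scaling, groups fitted alone, a filter of 5 CPM, at least 200 counts for single libraries, and leaving out each replicate. Keeping every row of the tables was not run separately, since no symbol was duplicated. In counts simulated from the brain and liver data with 200 changed genes, the average deletion fit recovered 85.1% of genes changed 2-fold and 98.5% of those changed 4-fold. The liver fit recovered 41.8% and 89.4%. The deletion fits in saline and in Aza recovered 47.8% and 50.7% of genes changed 2-fold, and 4.48% and 13.4% of those changed 1.5-fold. Counts for these fits were simulated without the pairing by replicate number, and 200 changed genes make the adjusted threshold easier to reach. These shares may therefore not hold for the real data. There, Xist changed by more than 4-fold in saline and in Aza and was called by neither of these 2 deletion fits. Unchanged genes that were called numbered 3 (average deletion) and 6 (liver), and with the replicate block 15 and 24.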

Results

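The series comprised 13 groups of mouse libraries. Brains came from 7-week C57BL/6-129S1/SvImJ females. In them both copies of Xist, the RNA that silences 1 X chromosome in female cells, were deleted (del/del) or carried loxP sites without deletion (2lox/2lox). Each genotype had received Aza, an inhibitor of DNA methylation, or saline, in 3 intraperitoneal injections given 2 days apart from 5 weeks of age. There were 3 del/del Aza, 3 del/del saline, 3 2lox/2lox Aza and 2 2lox/2lox saline brains. Livers came from 2lox/2lox Nestin-Cre mice, 3 after Aza and 3 after saline. Another 4 brains, 1 per group, came from untreated mice aged 75 weeks (del/+ and 2lox/+) or 91 weeks (del/del and 2lox/2lox). The 3 embryonic fibroblast libraries, from a CAST/EiJ-129S1/SvImJ cross, had received scrambled LNA, scrambled LNA with Aza, or Xist LNA with Aza for 72 hours. LNA is a locked nucleic acid oligonucleotide used to knock down an RNA. Liver labels give Nestin-Cre, while the del/del brain labels do not mention Cre, so any Cre effect in brain could not be separated from deletion. Depth, in units of 1e+06 counts, was 5.74 to 13.6 in 7-week brains, 3.74 to 7.24 in livers, 13.6 to 15.9 in aged brains and 16 to 19.8 in fibroblasts.

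**Figure D1:**
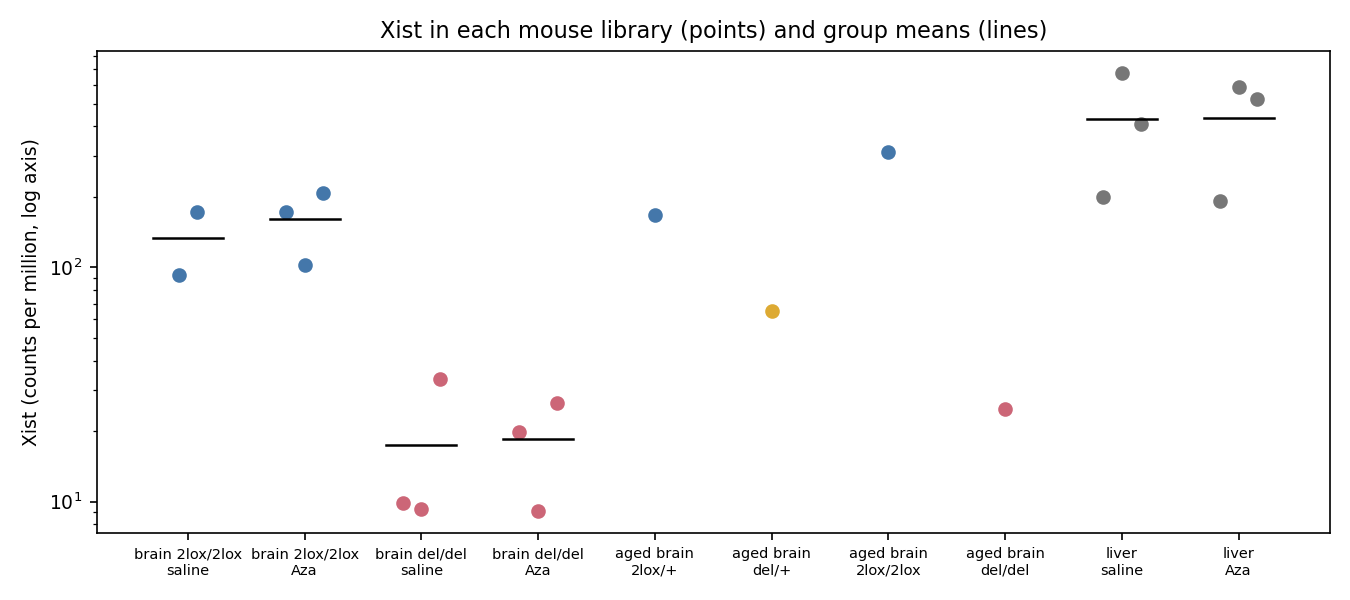
Xist in each tissue library, in CPM by total counts on a log axis, by group, with lines at group means. The del/del brains lie below all 2lox/2lox brains of the same age.

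The effect of Xist deletion on brain was averaged over both treatments. Xist (mm9 chromosome X, 100655712 to 100678572) stood at 17.8 ± 10.1 counts-per-million (CPM; SD, n = 6) in del/del brains and 151 ± 50.4 CPM (n = 5) in 2lox/2lox brains. Xist fell by 3.05 on the log2 scale (SE 0.38, edgeR adjusted p = 0.0371). Myoc, which encodes the secreted protein myocilin (chromosome 1, 164569281 to 164579825), rose 3.7-fold (log2 1.89, SE 0.24, adjusted p = 0.0371). Its level was 16.7 ± 5.59 CPM in deleted and 4.53 ± 0.888 CPM in 2lox/2lox brains, with all 6 deleted brains above all 5 others. No other gene passed, while 314 of 15284 had an unadjusted p under 0.05. Chance gives a share of 0.05 at this threshold, so these genes are no surplus. The same holds for the main edgeR counts at this threshold in the other brain comparisons and the liver.

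Listed escapees, genes transcribed from the otherwise silent X, were higher after deletion. Of the 15 measured, 13 lay above 0 with a median log2 change of 0.37, and 6 passed when adjusted over the list alone, against 0 of them over all genes. The camera adjusted p was 2.95e-12, and the adjusted p = 0.314 with an estimated correlation. Kdm5c, a histone H3K4 demethylase, stood at 223 ± 17.5 CPM in deleted and 159 ± 14.6 CPM in 2lox/2lox brains. Ddx3x, an RNA helicase, stood at 332 ± 45.6 against 257 ± 16.8 CPM, and 1810030O07Rik at 29.6 ± 3.77 against 19.2 ± 2.93 CPM. Each of Kdm5c and Ddx3x was higher in all 6 deleted brains than in any 2lox/2lox brain. Their log2 changes were 0.49 (SE 0.09, adjusted p = 0.214) and 0.38 (SE 0.10, adjusted p = 1). The index of escapees per library was 0.324 higher after deletion (exact permutation p = 0.025, adjusted p = 0.2 over 8 comparisons). It was higher in 5 of 5 same-numbered pairs (paired exact p = 0.0625, the smallest possible).

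The other 517 X-linked genes lay 0.0687 above autosomal genes on the log2 scale (camera p = 0.000173, p = 0.133 with an estimated correlation). Of them 343, or 66.3%, were above 0, compared with 50.1% of autosomal genes. Their index per library differed by 0.0623 (exact permutation p = 0.205) and was higher in 4 of 5 pairs. Mecp2, which encodes a reader of methylated DNA, did not pass (log2 -0.07, SE 0.08, unadjusted p = 0.401). Its level was 217 ± 16.8 CPM (n = 6) against 229 ± 16.3 CPM (n = 5). Cdkl5, a neuronal kinase, gave -0.04 (SE 0.12), Fmr1, an RNA-binding regulator of translation, 0.00 (SE 0.09), and Dnmt1, the maintenance DNA methyltransferase, 0.01 (SE 0.07). The 35 measured X-linked disease genes were not called as a list, with 18 above 0. Ftx and Jpx, noncoding RNAs near Xist, gave 0.92 (SE 0.35, adjusted p = 1) and 0.57 (SE 0.27, adjusted p = 1). Both were among the listed escapees and not among the 517 genes. Gpm6b, an X-linked membrane glycoprotein gene, stood at 431 ± 57.5 against 282 ± 21.2 CPM (log2 0.62, SE 0.10, adjusted p = 0.12).

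**Figure D2:**
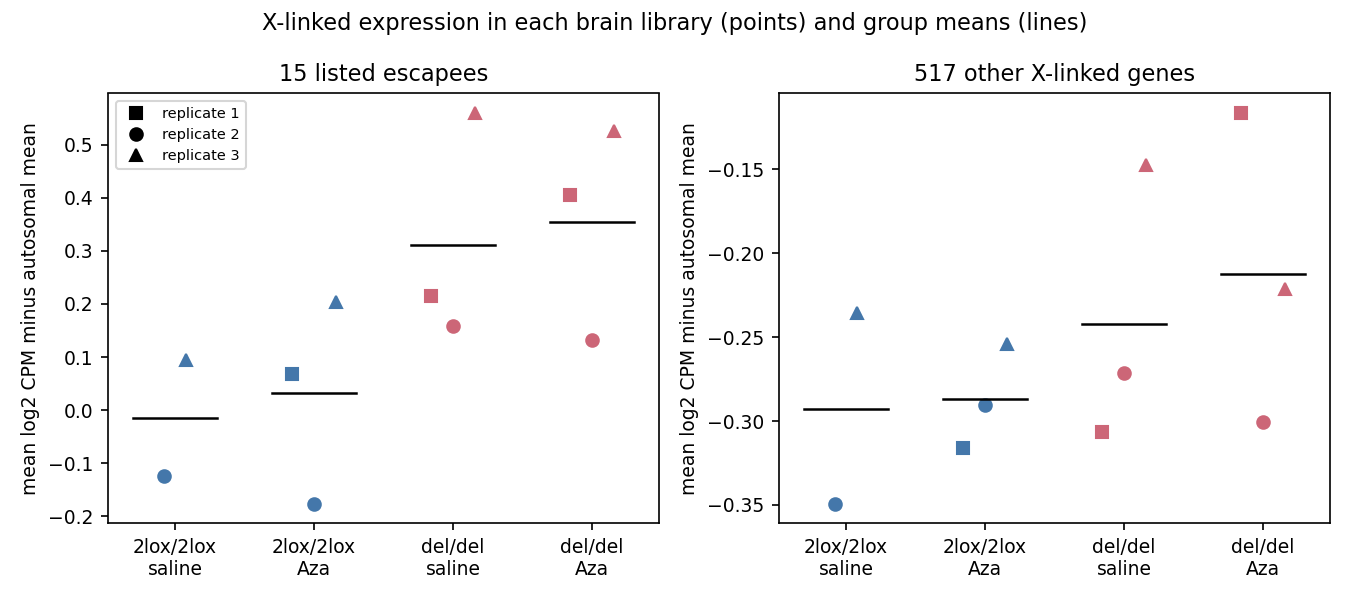
Mean log2 CPM of listed escapees (left, 15 genes) and other X-linked genes (right, 517 genes) minus that of autosomal genes, per 7-week brain library by group. Markers give the replicate number and lines the group means. Group means of escapees are higher in del/del than in 2lox/2lox brains.

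Red cell genes rose with deletion. Of 10 measured, 9 lay above 0 with a median log2 change of 0.88, and 7 passed when adjusted over the list alone, against 0 over all genes (camera adjusted p = 1.15e-18, adjusted p = 0.069 with an estimated correlation). Hba-a1, an alpha globin, stood at 18.5 ± 3.48 CPM in deleted and 9.59 ± 1.33 CPM in 2lox/2lox brains, and Hbb-b1, a beta globin, at 45.2 ± 7.02 against 25.2 ± 4.63 CPM. Overlapping globin genes share reads, and with 1 gene per overlapping pair and without X-linked Alas2 the median of 6 genes was 0.54. Meningeal genes were higher (13 of 15 above 0, median 0.18, camera adjusted p = 0.000208, adjusted p = 0.454 with an estimated correlation), with Igf2, a growth factor, at 110 ± 7.37 against 81.9 ± 10.7 CPM. Astrocyte genes were higher (9 of 13 above 0, median 0.07, adjusted p = 0.0442, adjusted p = 0.454 with an estimated correlation), with Gfap, an astrocyte filament protein, at 241 ± 24 against 178 ± 12.1 CPM. Lists lower after deletion were synapse (19 of 25 below 0, adjusted p = 0.014), excitatory neuron (10 of 12, adjusted p = 0.0322) and oligodendrocyte precursor (7 of 9, adjusted p = 0.0378) genes. With an estimated correlation these gave adjusted p = 0.943, adjusted p = 0.943 and adjusted p = 0.353. Replicate 1 brains, alone high in cerebellar Gabra6, made up more of the deleted brains, as 2lox/2lox saline has no replicate 1. Of the 314 list tests in brain and liver, 42 were called and 0 with an estimated correlation. DNA methylation, X silencing, germline, imprinted, interferon and p53 target genes were not called here.

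With the replicate block, 13 genes were higher and 2 lower, among them Ftx (log2 0.95, adjusted p = 0.00386) and Kdm5c (0.49, adjusted p = 0.00986), and DESeq2 called 19. Without any 1 brain other than del/del saline replicate 3, the main count of 2 dropped to 0, or to 1 (Myoc) without del/del saline replicate 2.

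In saline-treated mice the deletion left Xist at 17.3 ± 13.3 CPM (n = 3) compared with 134 ± 55.1 CPM (n = 2). The Xist log2 change was -2.94 (SE 0.55, edgeR adjusted p = 0.698), and that of Myoc 2.08 (SE 0.36, adjusted p = 0.568). Escapees were higher (13 of 15 above 0, median 0.28, 3 adjusted over the list alone and 0 over all genes, camera adjusted p = 2.15e-08, adjusted p = 0.455 with an estimated correlation), with Pbdc1 at 0.61 (SE 0.17) and 1810030O07Rik at 0.72 (SE 0.19). Red cell genes were higher in 10 of 10 (median 0.98, adjusted p = 1.02e-18, adjusted p = 0.0685 with an estimated correlation), with Hba-a1 at 1.21 (SE 0.21). Hypothalamic genes were lower in 10 of 11 (median -1.10, adjusted p = 1.18e-05, adjusted p = 0.702 with an estimated correlation), with Hcrt, the orexin precursor, at -2.34 (SE 0.97). Choroid plexus genes were lower in 14 of 14 (median -0.43, adjusted p = 1.18e-05, adjusted p = 0.708 with an estimated correlation). The del/del saline replicate 3 brain stood apart, with choroid plexus Ttr at 5.7 CPM, compared with 409 CPM in replicate 2 of that group. The X-linked genes lay 0.0565 above autosomal genes (p = 0.00551, p = 0.249 with an estimated correlation). At the preset correlation the shift was -0.0058 (p = 0.772) without 2lox/2lox saline replicate 2 and 0.0027 (p = 0.575) without del/del saline replicate 3. The index per library of these genes differed by 0.0505 (exact permutation p = 0.6). By edgeR 0 genes passed and 221 had an unadjusted p under 0.05, while the replicate block called 10, including Xist, Myoc and Ftx, and DESeq2 called 7.

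The effect of deletion under Aza was compared in 3 brains per group. Xist stood at 18.3 ± 8.71 against 163 ± 55.2 CPM, a log2 change of -3.16 (SE 0.53, edgeR adjusted p = 1). Myoc gave 1.69 (SE 0.31, adjusted p = 1) and Gpm6b 0.66 (SE 0.13, adjusted p = 1). Escapees were higher in 12 of 15 (median 0.37, 3 adjusted over the list alone and 0 over all genes, camera adjusted p = 3.59e-08, adjusted p = 0.718 with an estimated correlation). Eif2s3x, a translation initiation factor subunit, gave 0.55 (SE 0.15) and Kdm5c 0.47 (SE 0.12). Red cell genes were higher in 8 of 10 (median 0.73, adjusted p = 7.83e-10, adjusted p = 0.358 with an estimated correlation). Cholesterol synthesis genes were lower in 14 of 19 (adjusted p = 0.00828, adjusted p = 0.929 with an estimated correlation), with Dhcr24 at -0.30 (SE 0.12) and Ldlr at -0.35 (SE 0.13). Choroid plexus, meningeal and immediate early genes were also called higher (adjusted p = 0.0116, 0.0199 and 0.0369), each with an adjusted p = 0.929 with an estimated correlation. The 2lox/2lox Aza replicate 3 brain was low in Ttr, at 12.7 CPM against 355 CPM in replicate 2 of its group. The shift of X-linked genes was 0.081 (p = 0.0025, p = 0.213 with an estimated correlation), and 0.0315 (p = 0.481) without del/del Aza replicate 1. Their index per library differed by 0.0742 (exact permutation p = 0.3). By edgeR 0 genes passed and 260 had an unadjusted p under 0.05, and 778 genes did not overlap between groups, where chance gives 10% of genes. The replicate block called 2 (Xist and Myoc), and DESeq2 called 3.

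The joint effect of deletion and Aza was taken from del/del Aza brains (n = 3) and 2lox/2lox saline brains (n = 2). Xist gave -2.87 (SE 0.55), Myoc 1.80 (SE 0.36), Gpm6b 0.72 (SE 0.15) and Glipr2 1.29 (SE 0.25), with edgeR adjusted p = 0.999 for each of these. Escapees were higher in 13 of 15 (median 0.45, 2 adjusted over the list alone and 0 over all genes, camera adjusted p = 1.77e-09, adjusted p = 0.364 with an estimated correlation), with Kdm5c at 0.50 (SE 0.13) and Ddx3x at 0.45 (SE 0.15). Red cell genes were higher in 9 of 10 (median 0.94, adjusted p = 4.45e-15, adjusted p = 0.123 with an estimated correlation) and meningeal genes in 14 of 15 (adjusted p = 2.05e-06, adjusted p = 0.364 with an estimated correlation). Hypothalamic genes were lower in 10 of 11 (adjusted p = 0.00424, adjusted p = 0.866 with an estimated correlation). Single brains stood apart in them, with Pmch at 60.8 CPM in 2lox/2lox saline replicate 3 and 17.9 CPM in replicate 2, compared with 24.8, 22.3 and 10.3 CPM in del/del Aza brains, and Hcrt at 3.96 and 2.59 CPM compared with 1.17, 1.48 and 0.0919 CPM. Mecp2 gave 0.01 (SE 0.12), Cdkl5 0.01 (SE 0.17) and Fmr1 0.07 (SE 0.13). The X-linked shift was 0.082 (p = 0.000322, p = 0.147 with an estimated correlation), and 0.0388 without del/del Aza replicate 1 (p = 0.101) or without 2lox/2lox saline replicate 2 (p = 0.22). Their index per library differed by 0.0799 (exact permutation p = 0.4). By edgeR 0 genes passed and 188 had an unadjusted p under 0.05, the replicate block called 2 and DESeq2 called 3.

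The effect of Aza on brain was compared within each genotype. In del/del brains, Fmo1, a flavin monooxygenase gene, gave 0.60 (SE 0.16), Scube2, a secreted EGF-domain protein gene, 1.05 (SE 0.31) and Il2rb, a cytokine receptor gene, 2.14 (SE 0.73), with edgeR adjusted p = 1 for each. Xist gave 0.07 (SE 0.51), Mecp2 0.04 (SE 0.11) and Dnmt1 -0.05 (SE 0.09). Escapees lay above 0 in 9 of 15 (median 0.05, camera adjusted p = 0.903), germline genes in 3 of 7, imprinted genes in 13 of 29 and p53 target genes in 12 of 26. Interferon genes had 12 of 22 above 0, with a median of 0.08 and a mean of -0.05. No list was called, and with the replicate block choroid plexus genes were (median 0.42, adjusted p = 0.0257, adjusted p = 0.891 with an estimated correlation). By total counts, choroid plexus Ttr was at 5.83 CPM in del/del saline replicate 3, and at 324 to 407 CPM in the other del/del brains. X-linked genes were shifted by 0.0255 (camera p = 0.226), and their index per library by 0.0294 (exact permutation p = 0.6). At the preset correlation the shift was 0.0728 (p = 0.0117) without del/del Aza replicate 2 and 0.0776 (p = 0.00206) without del/del saline replicate 3. The direction turned without del/del Aza replicate 1, at -0.0164. In replicates 2 and 3 only, the shift was also negative and passed the threshold at the preset correlation. By edgeR 0 genes passed and 103 had an unadjusted p under 0.05, and DESeq2 called 0.

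In 2lox/2lox brains, Aza was compared in 3 against 2 libraries. Scube2 gave -1.55 (SE 0.34), Dmbx1, a homeobox gene, 3.13 (SE 0.82) and Lars2, the mitochondrial leucyl-tRNA synthetase gene, 1.36 (SE 0.37), with edgeR adjusted p = 1 for each. Hypothalamic genes were lower in 11 of 11 (median -1.24, camera adjusted p = 9.57e-08) and choroid plexus genes in 13 of 14 (median -0.47, adjusted p = 1.43e-06), with Hcrt at -2.06 (SE 0.97), Pomc, a pituitary hormone precursor, at -1.27 (SE 0.59) and Ccdc153 at -1.54 (SE 0.46). Microglial genes were lower in 14 of 16 (adjusted p = 0.0055), and meningeal and red cell genes were higher (both adjusted p = 0.0359). Each of these 5 calls was lost with an estimated correlation, at adjusted p = 0.813. The hypothalamic neuropeptide Pmch differed between libraries, from 0.462 CPM in 2lox/2lox Aza replicate 3 to 60.8 CPM in 2lox/2lox saline replicate 3. X-linked genes were shifted by 0.001 (camera p = 0.473 at the preset correlation). In the same test with the preset correlation the shift was 0.048 (p = 0.0296) without 2lox/2lox saline replicate 3 and -0.0656 (p = 0.242) without 2lox/2lox saline replicate 2. Their index per library differed by 0.0057 (exact permutation p = 1). By edgeR 0 genes passed and 187 had an unadjusted p under 0.05, the replicate block called 0, and DESeq2 called 1, germline Sycp1.

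Averaged over genotypes, Aza gave no called gene in edgeR, with 106 genes at an unadjusted p under 0.05, 0 called with the block and 2 by DESeq2 (Magi1 and Sycp1). Magi1, a scaffold protein of cell junctions, gave -0.26 (SE 0.06), Hdhd3 0.48 (SE 0.13) and Lars2 0.86 (SE 0.25), each with adjusted p = 1. Xist gave 0.18 (SE 0.37), Mecp2 0.08 (SE 0.08) and Dnmt1 0.03 (SE 0.07). Hypothalamic genes were lower in 11 of 11 (median -0.48, camera adjusted p = 0.0103), meningeal genes were higher in 14 of 15 (adjusted p = 0.0103) and microglial genes lower in 12 of 16 (adjusted p = 0.0427), each at adjusted p = 0.862 with an estimated correlation. X-linked genes were shifted by 0.0132 (camera p = 0.179), and their index per library by 0.0175 (exact permutation p = 0.65). At the preset correlation the shift passed without del/del Aza replicate 2 (0.0369, p = 0.0198), del/del saline replicate 3 (0.0392, p = 0.00582) or 2lox/2lox saline replicate 3 (0.0459, p = 0.0128).

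Whether Aza acted differently in the 2 genotypes was tested as an interaction. Scube2 gave a difference of 2.60 (SE 0.46, edgeR adjusted p = 1), at 4.47 ± 1.83 CPM in del/del Aza and 2.16 ± 0.401 CPM in del/del saline brains, compared with 1.98 ± 0.248 and 5.79 ± 0.681 CPM in 2lox/2lox brains. Hypothalamic genes (11 of 11 above 0, camera adjusted p = 8.95e-07) and choroid plexus genes (13 of 14, adjusted p = 5.17e-08) had a higher Aza effect in del/del brains, with Pmch at 2.60 (SE 1.39) and Ccdc153 at 1.73 (SE 0.62). Of these genes, Ttr was at 5.7 and 12.7 CPM and Pmch at 0.888 and 0.462 CPM in del/del saline replicate 3 and 2lox/2lox Aza replicate 3, compared with at least 288 and 10.3 CPM in the other 9 brains. Red cell genes (9 of 10 below 0, adjusted p = 0.0261) and cholesterol synthesis genes (16 of 19, adjusted p = 0.0135) had a lower one, with Hba-a2 at -0.48 (SE 0.28) and Ldlr at -0.30 (SE 0.20). All 4 were at adjusted p = 0.99 with an estimated correlation. X-linked genes differed by 0.0246 (camera p = 0.783 at the preset correlation). In replicates 2 and 3 only, this shift reversed to -0.0753 (camera p = 0.0125 at the preset correlation). Leaving out 1 library moved it from -0.0237 to 0.1102. By edgeR 0 genes passed and 181 had an unadjusted p under 0.05, and both the replicate block and DESeq2 called 0.

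The effect of Aza outside the brain was compared in livers (3 Aza, 3 saline). The 2 called transcripts were both lower. Both lay among the genes of the major urinary proteins (Mup), secreted carriers of pheromones made by the liver. Mup15 (chromosome 4, 60079341 to 60152730) stood at 0.354 ± 0.202 CPM (n = 3) after Aza and 42 ± 26.8 CPM after saline (log2 -6.75, SE 0.67, edgeR adjusted p = 0.0297). Its annotation spans those of Mup7 and Mup2, so these genes may hold the same reads. Gm2083 (60591133 to 60675237), whose annotation overlaps Mup10 and Mup11, stood at 0.0522 ± 0.0905 against 10.2 ± 1.38 CPM (log2 -7.12, SE 0.56, adjusted p = 0.00852). Mup17 did not pass at 0.308 ± 0.418 against 267 ± 194 CPM (adjusted p = 0.0779). Mup7 had 0 counts in all 3 Aza livers and 10.1 ± 5.97 CPM after saline (adjusted p = 0.19), while Mup18 gave -0.43 (SE 0.63) and Mup19 0.30 (SE 1.12), each with adjusted p = 1. Cyp2d9, a cytochrome higher in male livers, stood at 169 ± 22.4 against 432 ± 78 CPM (log2 -1.36, SE 0.17, adjusted p = 0.101). Genes with sex-biased liver expression were lower as a list (13 of 22 below 0, 5 lower adjusted over the list alone and 0 over all genes, camera adjusted p = 0.011, adjusted p = 0.476 with an estimated correlation). The list mixes genes higher in males, such as Cyp2d9, with genes higher in females, such as Sult2a1. Its direction therefore does not describe a change in sex bias. Saline replicates 1 and 3 stood apart from the other 4 livers in some genes of this list. In CPM by total counts, Slco1a1, a transporter higher in males, was at 100 and 162 in these 2, compared with 1.1 in saline replicate 2 and at most 0.14 after Aza. Sult2a1, a sulfotransferase higher in females, was at 6.04 and 3.48 in these 2, and at 298 to 403 in the other 4. Cyp2b9, a cytochrome higher in females, did not follow that grouping, at 0.38 in saline replicate 1 and 178 in saline replicate 3, with 0 in Aza replicate 3 and 473 to 538 in the other 3 livers.

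Interferon response genes were lower after Aza in 24 of 27 (median -0.39, 1 adjusted over the list alone and 0 over all genes, adjusted p = 1.41e-09, adjusted p = 0.476 with an estimated correlation). Irf7, a regulator of interferon genes, stood at 14.6 ± 3.5 against 28.4 ± 3.77 CPM, and Stat1, a transducer of interferon signals, at 46.4 ± 4.67 against 63.6 ± 4.39 CPM. Cholesterol synthesis (15 of 19 above 0), fatty acid oxidation (16 of 23) and gluconeogenesis (9 of 11) genes were higher, each at adjusted p = 0.026 and at adjusted p = 0.861 with an estimated correlation. Cyp4a14, a fatty acid hydroxylase, stood at 1639 ± 217 against 1054 ± 308 CPM and Igfbp1, a binding protein of growth factors, at 446 ± 84 against 293 ± 65.3 CPM. Xist stood at 431 ± 207 against 429 ± 228 CPM, Mecp2 gave 0.15 (SE 0.19), and escapees had 12 of 15 below 0 (adjusted p = 0.434). X-linked genes were shifted by 0.0118 (camera p = 0.822) and their index per library by 0.0123 (exact permutation p = 0.5). Imprinted and p53 target genes were not called, and 2 germline genes were too few to test.

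In the liver, edgeR called 0 genes higher and 2 lower, with 365 at an unadjusted p under 0.05, compared with 13 lower with the replicate block and 33 by DESeq2, and 925 genes did not overlap, where chance gives 10%. The count was 52 without saline replicate 2, 0 without Aza replicate 1, Aza replicate 2 or saline replicate 1, and 1 (Gm2083) without Aza replicate 3.

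**Figure D3:**
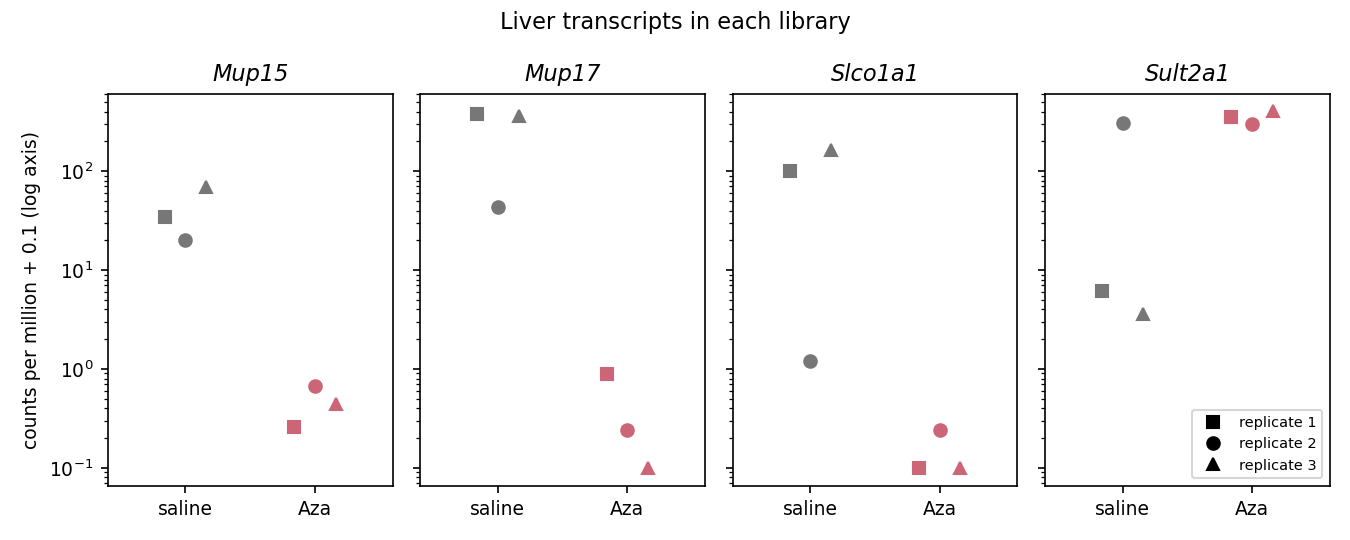
Mup15, Mup17, Slco1a1 and Sult2a1 in each liver by treatment, in CPM by total counts plus 0.1 on a log axis, with markers giving the replicate number. Slco1a1 is high and Sult2a1 low in saline replicates 1 and 3 alone.

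Xist deletion at 75 or 91 weeks was compared in single aged brains, with no replicates. Xist was 13.1-fold lower (11.8 to 14.5) in the del/del than in the 2lox/2lox brain, at 24.3 and 317 CPM. In the del/+ brain it was 0.407 of the 2lox/+ level (0.378 to 0.439). Mecp2 was 0.916 (0.875 to 0.958) and 1.01 (0.959 to 1.05) of control. The median of escapees was 0.19 in del/del, at percentile 95 of random lists, and 0.095 in del/+, at percentile 89.7, with Kdm5c 1.4-fold (1.33 to 1.48) and Eif2s3x 1.68-fold (1.33 to 2.13) higher in del/del. Other X-linked genes had medians of -0.04 (percentile 1.75) and -0.02 (percentile 19.2).

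In the 91-week pair, genes of microglia, the brain's resident macrophages, were higher in del/del for 16 of 16 (median 1.39). Trem2, a microglial lipid receptor, was 9.04-fold (7.46 to 11) and C1qa, a complement component, 7.58-fold (6.88 to 8.35) higher. Gpnmb, a glycoprotein of phagocytic cells, was 38.9-fold (31.8 to 48.1) higher, and Cst7 had 591 counts against 3. Interferon genes were higher in 22 of 23 (median 0.74) and astrocyte genes in 12 of 13 (median 0.66), with Gfap 6.87-fold (6.64 to 7.12) higher. Other cell types were higher too, with oligodendrocyte genes in 15 of 15 (median 0.67), oligodendrocyte precursor genes in 7 of 9 (median 0.82) and choroid plexus genes in 14 of 14 (median 0.99), while meningeal genes had 4 of 15 above 0 (median -0.39). Immediate early genes had 1 of 20 above 0 (median -0.83), with Arc, a synaptic activity marker, at 0.368 of control (0.353 to 0.383). Beside them, excitatory neuron genes had 2 of 12 above 0 (median -0.76), inhibitory neuron genes 4 of 14 (median -0.26) and synapse genes 1 of 25 (median -0.48). Region-specific transcripts also differed in this pair. Thalamic and midbrain genes were higher in 11 of 11 (median 2.12), with the dopamine transporter Slc6a3 at 699 against 2 counts, hypothalamic genes in 7 of 7 (median 2.37), striatal genes in 12 of 13 (median 0.64) and cerebellar genes in 8 of 10 (median 0.75). In all, 654 genes were at least 2-fold higher and 137 lower of 12548.

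In the 75-week pair, immediate early genes were higher in del/+ for 20 of 20 (median 0.75), with Fosb 2.72-fold (2.47 to 3) and Egr4 2.41-fold (2.27 to 2.56) higher. Excitatory neuron genes were higher in 10 of 12 (median 0.59), inhibitory neuron genes in 9 of 14 (median 0.51) and synapse genes in 21 of 25 (median 0.18). Microglial genes were higher in 14 of 16 (median 0.54), with Itgax at 5.6-fold (3.83 to 8.41). Meningeal genes were higher in 14 of 15 (median 1.03) and oligodendrocyte genes had 0 of 15 above 0 (median -0.67), with the myelin protein gene Mog at 0.541 of control (0.492 to 0.594). Thalamic and midbrain genes had 0 of 11 above 0 (median -2.18), with Slc6a3 at 3 against 1029 counts, and striatal and cerebellar genes 4 of 13 (median -0.43) and 3 of 10 (median -0.44). Choroid plexus genes had 0 of 14 above 0 (median -1.51), with Ttr at 0.268 of control (0.255 to 0.282). Here 113 genes were at least 2-fold higher and 202 lower of 12326.

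In fibroblasts, the question was how Aza and loss of Xist act on the silent X. In the scrambled LNA control 96.9% (96.2 to 97.5) of allelic Xist reads came from the mus allele. Xist counts were 8470 in the control, 6507 with Aza (ratio 0.616, 0.597 to 0.636) and 921 with Xist LNA and Aza, 7.3-fold lower (6.82 to 7.83) than with Aza alone. Over 280 X-linked genes with a mus share of 50% or less in the control, the mus share was 3.3% (3.17 to 3.42) in the control, 3.67% (3.55 to 3.8) with Aza and 4.73% (4.59 to 4.87) with Xist LNA and Aza. Of these, 13 listed escapees had shares of 7.57% (6.98 to 8.19), 10.1% (9.47 to 10.8) and 14.1% (13.4 to 14.9). Gene by gene, 9 of the 13 had a higher share with Xist LNA and Aza than in the control and 4 a lower one, with 4 higher and 0 lower beyond their intervals. Compared with Aza alone, 7 had a higher and 6 a lower share, with 3 higher and 0 lower beyond their intervals. Bgn alone held 3907 of the 7506 allelic reads of these escapees in the control, at a mus share of 0.589%. The other 267 genes had 2.85% (2.73 to 2.97), 3.01% (2.89 to 3.13) and 3.71% (3.58 to 3.84). Per 1e+06 autosomal reads of the same allele, these 267 genes had 855.5, 825.3 and 1002 mus reads and 32090, 29540 and 29370 CAST/EiJ reads, so the share with Aza alone went up while both alleles went down. The escapees had 237.7, 286 and 411.1 mus reads and 3195, 2823 and 2828 CAST/EiJ reads. Autosomal shares were 52.4%, 52.6% and 53.1%. Between the control and Xist LNA with Aza, 12 of these 280 genes (4.29%) gained mus share beyond their intervals and 0 lost it, compared with 2.73% and 2.9% of autosomal genes. The 0 says little, since 106 of the 280 had no mus read in the control and could not lose share. By the share alone, 117 of the 280 were higher and 91 lower. Against Aza alone, Xist LNA with Aza gave 9 gains (3.21%) and 1 loss (0.357%) beyond the intervals, compared with 0.847% and 0.737% of autosomal genes. By the share alone, 135 of the 280 were then higher and 66 lower. Shares near 0 have narrower intervals than autosomal shares near 50%, so X-linked and autosomal rates are not directly comparable. With Aza alone against the control, 83 were higher and 117 lower, the median share went from 0.63% to 0.403%, and beyond their intervals 5 gained and 2 lost. The 10 X-linked genes above 50% in the control, left out here, had mus shares of 77.1%, 68.6% and 69.7%.

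Ddx3x went from a mus share of 16% (13.2 to 19) in the control to 23.9% (21 to 27) with Aza and 34.3% (31.3 to 37.4) with Xist LNA and Aza. Kdm5c went from 28.3% (25.4 to 31.4) to 38.8% (36.2 to 41.5). Uba1, a ubiquitin-activating enzyme gene, went from 0.622% (0.229 to 1.35) to 5.94% (4.88 to 7.15). Msn, which links membrane and actin, reached 4.23% (3.41 to 5.18) from 0.123%, and Lamp2, a lysosomal membrane protein gene, 4.23% (3.34 to 5.29) from 0.314%. Uba1, Msn and Lamp2 were chosen after their values were seen. Mecp2 had 0 of 395 mus reads in the control, which allows up to 0.759%, 3 of 513 with Aza (0.585%, 0.121 to 1.7), and 0 of 457 with Xist LNA and Aza, which allows up to 0.656%. Cdkl5 had 0 of 31 in the last, which allows up to 9.68%, and Fmr1 had 1 of 32 in the control and 2 of 52 in the last.

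**Figure D4:**
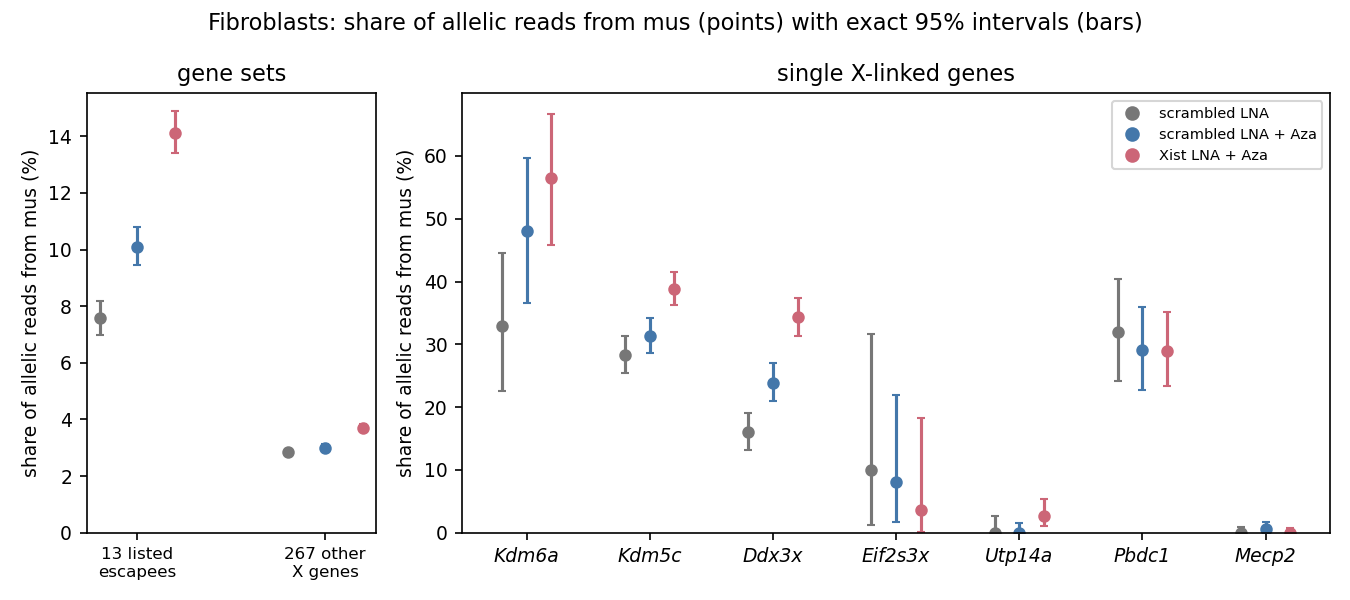
Share of allelic reads from the mus allele, in percent, with exact 95% intervals, in 3 fibroblast libraries, for 13 listed escapees and 267 other X-linked genes summed (left) and single genes (right). Shares of both sums are highest with Xist LNA and Aza.

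With Aza alone, 548 fibroblast genes were at least 2-fold higher and 582 lower of 11322. Interferon genes were higher in 28 of 30 (median 2.32), with Isg15, a ubiquitin-like antiviral modifier, 17.6-fold (12.8 to 25) higher. Germline genes, silenced by DNA methylation in somatic cells, were higher in 6 of 7, with Tex13 at least 27-fold and Tex19.1 at least 18.7-fold higher than a control with 0 counts. The p53 target genes were higher in 24 of 27 (median 0.83), with Mdm2, the p53 ubiquitin ligase, 2.75-fold (2.59 to 2.92) and Cdkn1a, a cell cycle inhibitor, 2.63-fold (2.49 to 2.77) higher. Cholesterol synthesis genes were higher in 19 of 19 (median 0.64). Imprinted genes had a median of -0.42, with H19 at 0.0828 of control (0.0768 to 0.0892) and Ndn 4.18-fold (3.63 to 4.82) higher. Extracellular matrix genes had a median of -0.28, with Postn at 0.135 (0.123 to 0.148), and Igfbp5 was 79.5-fold (71.6 to 88.5) lower. Total reads of X-linked genes had a median of -0.19, with 125 of 377 above 0, below all random lists.

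With Xist LNA under Aza, 20 genes were at least 2-fold higher and 10 lower of 11083 than with Aza alone. Interferon genes were higher in 32 of 32 (median 0.81, percentile 100), with Oas2, an antiviral enzyme, 3.8-fold (2.72 to 5.42) and Usp18, an inhibitor of interferon signalling, 2.85-fold (2.34 to 3.48) higher. Escapees were higher in 12 of 15 (median 0.18, percentile 100), with Car5b 1.45-fold (1.13 to 1.87) and 1810030O07Rik 1.34-fold (1.15 to 1.55) higher. Other X-linked genes had a median of 0.02 (percentile 98.7). Mecp2 was at 0.98 (0.928 to 1.04) and Dnmt1 at 0.984 (0.964 to 1) of the Aza level. Against the control, Xist LNA and Aza together gave 575 genes at least 2-fold higher and 656 lower of 11347, interferon genes higher in 32 of 32 (median 3.42), and Xist at 0.0844 (0.0787 to 0.0903). No library with Xist LNA and no Aza was among the data, so the effect of knockdown alone was not measured.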

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

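The tests of autosomal scaling, the missing replicate, strain segments, male mice and Mup copies were chosen only after the result was seen, while the regroupings and the test around Xist were planned. Reading the latter also with an estimated correlation and with the block was chosen after the result was seen. Hypothalamic genes stood out because the interaction of Aza and genotype passed its test for the list, with a median log2 difference of 1.78. Choroid plexus genes stood out in the same way, with a median of 0.77. Red cell genes differed with a median of -0.16, and cholesterol synthesis genes with a median of -0.16. None of these list calls held with an estimated correlation. The del/del saline replicate 3 and 2lox/2lox Aza replicate 3 brains were low in choroid plexus Ttr (5.7 and 12.7 CPM, compared with 288 to 409 CPM in the other 9).

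Escapees and other X-linked genes were higher in Xist-deleted brains. For the escapee mean (0.333), 3 of 100 regroupings gave a mean as large in either direction (highest other 0.3583). These regroupings ignore the replicate numbers, which pair the samples, so they cannot exclude chance. Exchanges within same-numbered pairs with the block are too few to tell in either direction, since exchanging all 5 pairs turns the sign. They gave 0.3249 against -0.3292, with 2 of 32 as large and 1 of 32 in the same direction. For the X-linked shift (0.0687) chance cannot be excluded, with 18 of 100 regroupings (highest other -0.1098) and, with the block, 6 of 32 exchanges as large as 0.0695 (highest other -0.0932), nor for the number of lists called (7), with 49 of 100 (highest other 17). Scaling from autosomal genes (0.0688) cannot change a difference between X-linked and autosomal genes, so it decides nothing, and the missing 2lox/2lox saline replicate 1 stays open, since replicates 2 and 3 alone gave 0.0518 (camera p = 0.0043 at the preset correlation, p = 0.219 with an estimated correlation). A segment inherited around Xist stays open for X-linked genes. They stood at 0.0604 over 20 Mb from Xist (camera p = 0.00209 at the preset correlation, p = 0.172 with an estimated correlation) and 0.1042 within. Such a segment stays open for escapees too, at 0.2009 over 20 Mb away (0.2076 with the block) and 0.5605 within. The escapees over 20 Mb away passed at the preset correlation in both fits. With an estimated correlation they passed only with the block. The length of such a segment was not measured, so genes over 20 Mb away may still lie on it. A direct effect of Xist loss or a Cre difference was not tested.

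For the 2 genes called for deletion on average, 4 of 100 regroupings gave as many, but these ignore the replicate numbers, and the 3 besides the real one called 515, 136 and 11. The regroupings with 515 and 136 set all replicate 2 brains against all replicate 3 brains, which points to a structure of the samples by number. With the replicate block, 1 of the 32 exchanges within the 5 same-numbered pairs, the real one, reached 15 genes (highest other 2). That is the smallest share 32 exchanges can give. The 15 include Xist, the deleted gene itself, and del/del saline replicate 1 has no partner and was never exchanged. Chance is therefore not excluded for the other genes. For the average Aza effect the count was 0, which 100 of 100 regroupings reach by construction, so this says nothing about chance, while 1 regrouping that also set all replicate 2 against all replicate 3 brains called 1820. Autosomal genes with an unadjusted p under 0.01 for deletion (134 with the block) lay together on chromosome 1. The most crowded 20 Mb window held 7 of them (permutation p = 0.0117). With the block the Aza contrast also gave a crowded window (permutation p = 0.0183). The labels call these mice F2, so strain segments may differ between the few Aza and saline brains too. The Aza contrast therefore cannot serve as a control for them. Without the block, deletion gave a crowded window (35 genes, permutation p = 0.0176) and Aza did not (9 genes, permutation p = 0.18). This difference decides nothing, also because 9 genes are few. The fits thus differ, and such segments could not be told apart from other causes of crowding.

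Of the 13 genes called lower in Aza livers with the block, 9 were Mup genes or Gm2083, while Mup18 and Mup19 were not called. Male mice among the saline livers are argued against by Xist, whose lowest level was 192 CPM by total counts, with 0 counts of Y-linked genes in any liver. Reads shared between Mup copies would not account for the 4 genes called with the block outside the family (Cyp2d9, Cyp2d12, Susd4 and Neb). These 4 genes cannot show whether Mup rows share reads, so that stays open for the other 9. Their count replaced a test in which 0 of 6 male-type genes had their 2 highest livers where Mup7 did. In that test, 12 of 16 Mup genes had theirs at saline replicates 1 and 3. An effect of Aza and a hormonal difference of saline replicates 1 and 3 both stay open, and either might contribute. For splits of 6 libraries into 3 and 3 the 10 possible are too few for a share under 0.05, with 2 genes in the real liver split, reached by 2 splits (highest other 3), and 0 for Aza in del/del brains (highest other 0) and for deletion under Aza (highest other 1), counts that all 10 splits reach by construction.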

How the results depend on the processing

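The settings that kept replicates 2 and 3 only (also with an estimated correlation), left out the 2 brains low in choroid and hypothalamic transcripts or the 2 saline livers with male-type transcripts, changed the limits on allelic reads, kept mus-biased genes or reduced the red cell list were chosen after seeing the data. Of the values of the comparisons under settings other than leaving out 1 library, 167 stayed the same, 21 were stronger, 14 weaker, 4 reversed and 5 moved. Of the 167, 9 were X-linked shifts with autosomal scaling, which cannot change them. For tests, stronger means newly past the threshold and weaker no longer past it. For counts of called genes or lists, they mean a larger or smaller count. Values from single libraries either stayed or moved. The cause was not tested unless stated. The replicate block, which removes the spread between replicate numbers, raised the called genes for deletion in saline to 10, in Aza to 2, with Aza to 2, on average to 15 and for the liver to 13. Among counts of genes and X-linked shifts it changed no other call, and of the list calls (42 without it, 59 with it) 35 were shared. DESeq2 called 1 (Aza in 2lox/2lox), 7 (deletion in saline), 3 (in Aza), 3 (deletion plus Aza), 2 (average Aza), 19 (average deletion) and 33 (liver). With no filter on low counts there were 1 (deletion in Aza), 7 (average deletion) and 36 (liver). Replicates 2 and 3 only gave 0 for average deletion, and with the block 11, with 5 in saline, 2 in Aza and 2 for deletion plus Aza. Without the 2 brains low in choroid and hypothalamic transcripts average deletion called 1. Without the 2 male-type saline livers the liver called 2.

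The X-linked shift was not past the threshold with an estimated correlation for deletion in saline (0.0565, p = 0.249), in Aza (0.081, p = 0.213), plus Aza (0.082, p = 0.147) and on average (0.0687, p = 0.133, and 0.0518, p = 0.219 in replicates 2 and 3 only). At the preset correlation it reversed in replicates 2 and 3 only for Aza in del/del (-0.0507, p = 0.012; with the block -0.0498, p = 0.00877) and the interaction (-0.0753, p = 0.0125; with the block -0.0738, p = 0.00922). It no longer passed there for deletion in Aza (0.0141, with the block 0.0164) and deletion plus Aza (0.0387, with the block 0.0404). Without the 2 brains low in choroid and hypothalamic transcripts it was 0.0765 for Aza in del/del, 0.003 for deletion in saline and 0.0295 for average Aza. No list call held with an estimated correlation, with the block (0) or without (0). At least 200 counts left 203 genes changed 2-fold in aged del/+ (315 before), as fewer genes were compared. Total-count scaling gave a fibroblast Xist ratio of 0.638 under Aza, and keeping mus-biased genes gave X-linked mus shares of 4.06%, 4.59% and 5.67%.

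Leaving out 1 library at a time, called genes ranged from 0 to 2 for average deletion and 0 to 52 for the liver, and stayed at 0 for the other 7 comparisons. X-linked shifts ranged from 0.0412 to 0.1099 (average deletion), -0.0058 to 0.1119 (deletion in saline), 0.0315 to 0.1282 (in Aza), 0.0388 to 0.1558 (plus Aza), -0.0164 to 0.0776 (Aza in del/del), -0.0656 to 0.048 (in 2lox/2lox), -0.0105 to 0.0459 (average Aza), -0.0237 to 0.1102 (interaction) and 0.0137 to 0.04 (liver). All 6 liver values lay above the 0.0118 of the full set because the filter then let through 11974 to 12161 genes instead of 11817, and over those 11817 genes the range was -0.0009 to 0.023, a check made after seeing this. Where this left 1 sample in a group, it was assumed to vary like the others. Some allele shares rest on few reads, as Cdkl5 had 22 to 33 allelic reads per library.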

Other observations

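The relation tests in this part were planned, and the chromosome shares were chosen only after the result was seen. Autosomal allele shares in fibroblasts were not even. The mus share was 73.1% on chromosome 14 and 66.1% on chromosome 8 in the control, and 76.4% and 69.5% with Xist LNA and Aza. On chromosome 1 it was 44.9% in the control and 40.6% with Aza. The Xist reads of the CAST/EiJ allele numbered 83 in the control, 166 with Aza and 22 with Xist LNA and Aza.

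Replicate 1 brains differed from the rest in cerebellar transcripts, among them the GABA receptor subunit gene Gabra6, chosen after their values were seen. Gabra6 stood at 125 CPM (del/del Aza), 111 CPM (del/del saline) and 88.8 CPM (2lox/2lox Aza), and at most at 0.592 CPM in the other 8 brains. By total counts, Pcp2 was at 61.7 to 73.6 CPM and Cbln3 at 275 to 296 CPM in replicate 1 brains. In the other 8 they reached at most 0.367 and 1.55 CPM. The 2lox/2lox saline group has no replicate 1, so without the block its comparisons also differ in cerebellar transcripts. Across genes, the deletion effects in saline and in Aza, which share no libraries, correlated at Pearson r = 0.864 for 15 escapees, 0.304 for 517 other X-linked genes and 0.032 for autosomal genes. Genes are not independent replicates.

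A hypothesis was that X-linked genes that gain reads from the silent X in fibroblasts after Xist knockdown gain more in brain after Xist deletion. Across 274 genes the change of mus share correlated with the brain deletion effect at Spearman rho = 0.128 (permutation p = 0.0337, adjusted p = 0.0899 over 8 relations) and Pearson r = 0.166 (p = 0.0102). Without listed escapees, rho was 0.151 (p = 0.0147). This is a weak relation that fails the correction, and it may reflect shared features of these genes. The control mus share itself gave rho = 0.07 (permutation p = 0.247), and -0.02 (p = 0.744) without listed escapees, which leaves open whether genes that escape more in fibroblasts gain more in brain.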
